A study of Homo sapiens with 12 samples.

How the data were processed

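Total RNA from 2 established human mantle cell lymphoma lines, Z-138 and Maver-1, was measured on 12 Affymetrix arrays that read the 3' part of transcripts. Per the labels, Z-138 has a nonsense change in TRAF2 and Maver-1 a TRAF3 deletion. Each line held a doxycycline-inducible hairpin in 3 versions, a non-targeting control (NTC) and 2 hairpins against MAP3K14, the gene of the kinase NIK, called NIKsh#1 and NIKsh#2. Each of the 6 puromycin-selected cultures was grown for 7 days with 0 or 100 ng/ml doxycycline and gave 1 array per condition. The RNA had been amplified and labelled with biotin.

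The deposited values were linear signal intensity per probe set, and the submitters' processing notes name MAS5 as the method. On every array the mean signal without the lowest and highest 2 percent of probe sets was 150.02, so the authors had scaled the arrays to a common trimmed mean. Array medians ran from 10.6 to 14.1, a 1.33-fold range that lay under the 1.5-fold limit set for rescaling, and no further normalization was applied. Signals were taken to log2(signal + 3). The pseudocount was the median over arrays of the 25th percentile of all probe sets, rounded to a whole number, and log2 changes on this scale understate the change of genes with low signal. Detection calls were not used here. The number of arrays limits the precision of every value.

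Of 54675 probe sets, 41097 had 1 gene symbol in the platform annotation, 1801 had several symbols and 11777 were not named in the annotation used here. Symbols and chromosomes follow the human RefSeq annotation of GRCh38. Of the probe sets with 1 symbol, the one with the highest mean log2 signal stood for its gene. Genes whose mean signal over the 12 arrays was under 12.55, the median of the array medians, were left out, which kept 11548 of 19775 genes. Probe sets with several symbols and 62 control probe sets were not tested. The control probe sets gave the ratio of 3' to 5' signal of ACTB and GAPDH on each array.

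Models were fitted with limma 3.58.1 in R 4.3.3, with two-sided moderated tests, an intensity trend in the variance and Benjamini-Hochberg adjustment over the 11548 genes at 0.05. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. Culture was a fixed block, because per the labels the cells carrying each construct were split between medium with and without doxycycline, so that the 2 arrays of a culture are a pair. This pairing was checked on the deviation of each NIKsh array from the mean of its group, which correlated across genes between the 2 arrays of a hairpin at -0.038 in Z-138 and 0.202 in Maver-1. Genes are not independent replicates in such a correlation, and in Z-138 it did not show the pairing. The first model had a doxycycline effect for the 4 NIKsh cultures, another for the 2 NTC cultures, and their difference, with 4 residual degrees of freedom. A second model had an effect per line and knockdown (2 residual degrees of freedom), and another an effect per hairpin (3 residual degrees of freedom). The 6 untreated arrays were compared between lines (3 cultures each) and, with the line as a term, between NIKsh and NTC cultures. Each standard error is that of the limma model. The p-values measure only the spread between these cultures. The samples, comparisons, gene lists and alternatives were fixed before the data were examined, apart from those named below as added.

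The genes named are, per comparison, the 12 highest and 12 lowest log2 changes among genes that passed with the same sign in every pair, or without overlap between the groups for the 2 untreated comparisons, and 6 each way in the NTC, line, hairpin and untreated hairpin comparisons. Where fewer passed, places were filled by smallest p from genes at least 1.5-fold apart the same way in every pair, or on average and without overlap for the untreated comparisons, and these are given as values that did not pass. MAP3K14, the components of the alternative NF-kB pathway and up to 4 members of each list with the smallest p could also be named. Genes chosen after their values were seen are said to be so. Genes at least 1.5-fold apart the same way in all 4 NIKsh cultures were counted without a test and set against the other 7 sign patterns of the 4 pairs.

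In all, 25 gene lists with at least 5 measured genes were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists, then with an estimated correlation and with fry, which asks whether the genes of a list move one way on balance. The lists were alternative NF-kB pathway components, canonical NF-kB pathway components, NF-kB target genes, chemokines and homing, B cell identity and B cell receptor signalling, plasma cell differentiation, MHC class II, MHC class I, interferon response, S phase, G2/M phase, MYC targets, apoptosis, p53 targets, the ATF4 stress response, endoplasmic reticulum chaperones, cholesterol synthesis, glycolysis and hypoxia, respiratory chain, mitochondrial ribosome, mantle cell lymphoma features with D-type cyclins, T and NK cell markers, monocyte markers, fibroblast, epithelial and endothelial markers, and histone and RNA-interference genes. Some genes stand in several lists, and 54 of 770 written entries matched no symbol. For single values per culture, exact permutation tests compared the 4 NIKsh with the 2 NTC cultures, two-sided, with 0.0667 as the smallest possible p, or flipped the signs of the 4 NIKsh pairs, with 0.125 as the smallest.

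The alternatives were no culture block, culture as a random block, quantile normalization, a pseudocount of 1 or of 4 times the one used, no filter, a filter at the 75th percentile, averaged or separate probe sets, no variance trend, array weights, the other set tests, a 2-fold limit, subtraction of the NTC pair, effects averaged over the lines, and leaving out each culture. Added after seeing the data were the ACTB ratio as a covariate, a pseudocount of 16 with a mean signal of at least 50, the counts per line and the lists between untreated lines.

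The models were tested on simulated data with the residual spread of each gene and 200 changed genes. At 1.5-fold, 2-fold and 4-fold, the NIKsh model recovered 35.8%, 71.6% and 93.9% of changed genes, the NTC effect 10.4%, 50.7% and 80.3%, and their difference 1.5%, 14.9% and 66.7%. Between lines, 0%, 0% and 1.5% of changed responses were recovered, and between hairpins 0%, 6% and 33.3%. In these models the spread of each gene was itself estimated from few residual degrees of freedom, so the shares may understate the power. The measured data gave 14 genes between lines, with a median log2 size of 2.12. The simulated shares therefore cannot be read as the power of the line comparison. The untreated lines gave 40.3%, 77.6% and 98.5%, and the untreated NIKsh cultures against NTC 25.4%, 77.6% and 95.5%. False calls ran from 0 to 7 per comparison. With no gene changed, 8 genes met the 1.5-fold rule in all 4 cultures. Camera at the preset correlation was tried with the MHC class II list lowered 1.25-fold. It called that list, and also 1 of the 23 unshifted lists that shared no gene with it. The simulated genes varied independently, so false list calls among correlated genes were not measured.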

Results

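Gene expression after induced knockdown of MAP3K14 was measured in Z-138 and Maver-1, 2 lines of mantle cell lymphoma, a B cell tumour. MAP3K14 encodes NIK, the kinase that starts the alternative NF-kB pathway, and TRAF2 and TRAF3, which the labels give as altered in Z-138 and Maver-1, hold NIK protein low in resting cells. The 12 arrays fell into 8 groups by line, knockdown and doxycycline. Each of the 4 NTC groups held 1 array and each of the 4 NIKsh groups held 2 arrays, 1 per hairpin. The median signal per array lay between 10.6 and 14.1 and the 75th percentile between 109.8 and 126.9. Values below are log2 changes of a culture with doxycycline against the same culture without it, unless a comparison says otherwise, and errors are standard errors of the limma model.

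The 3' to 5' signal ratio of ACTB, a sign of RNA integrity and amplification, differed between arrays. In Z-138 it was higher with doxycycline in all 3 cultures, at 2.33 and 6.34 in NTC, 2.86 and 4.62 in NIKsh#1, and 2.92 and 5.09 in NIKsh#2. In Maver-1 it was 6.88 without and 4.43 with doxycycline in NTC, 4.68 and 4.32 in NIKsh#1, and 3.66 and 3.8 in NIKsh#2. The GAPDH ratio without and with doxycycline was 1.17 and 2 in Z-138 NTC and 1.15 and 1.83 in Z-138 NIKsh#2. In Z-138 NIKsh#1 it was nearly flat at 1.3 and 1.36, unlike that of ACTB. In Maver-1 it was 2.39 and 1.68 in NTC, 1.63 and 1.58 in NIKsh#1, and 1.54 and 1.42 in NIKsh#2. The SD over genes of the doxycycline change was 0.541, 0.46 and 0.513 in Z-138 NTC, NIKsh#1 and NIKsh#2, and 0.264, 0.301 and 0.351 in the Maver-1 cultures.

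**Figure D1:**
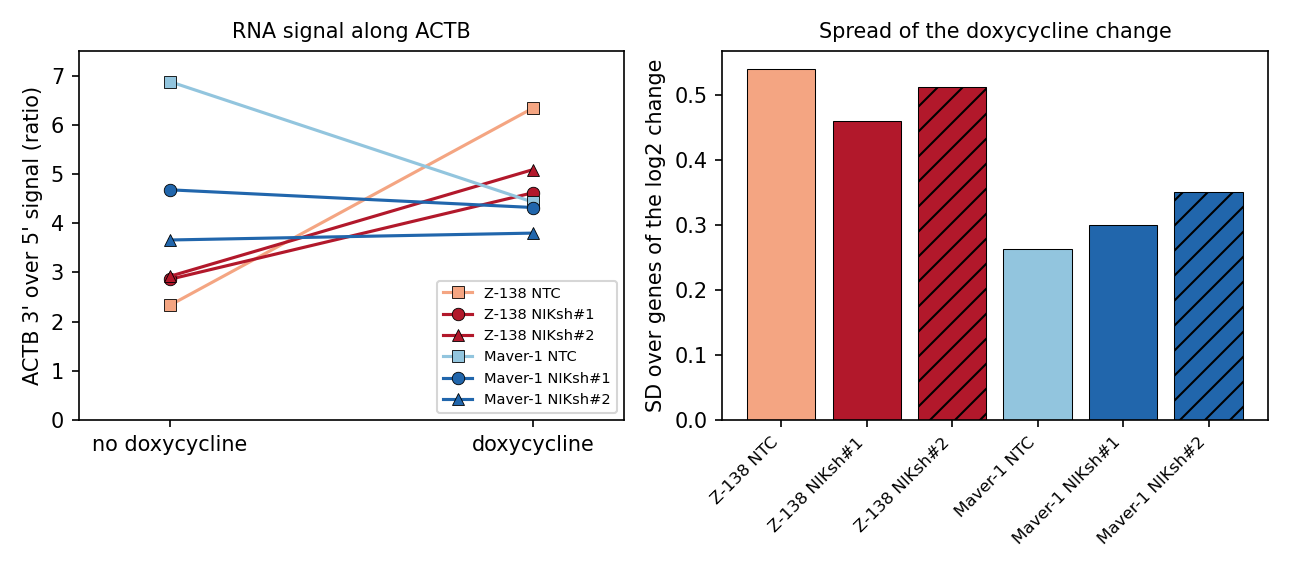
Left, ratio of 3' to 5' ACTB signal per array (no unit, linear axis) without and with doxycycline, with a line joining the 2 arrays of each of the 6 cultures. Right, SD over 11548 genes of the log2 doxycycline change per culture as bars, from 0.264 in Maver-1 NTC to 0.541 in Z-138 NTC.

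The first question was whether the hairpins lowered their target. MAP3K14 (chromosome 17, measured by its only probe set) had a mean log2 change of -0.42 with an SD of 0.25 in the 4 NIKsh cultures, and of 0.50 with an SD of 0.37 in the 2 NTC cultures. With doxycycline its signal went from 55.2 to 33.3 in Z-138 NIKsh#1, from 52.0 to 49.2 in Z-138 NIKsh#2, from 86.9 to 63.4 in Maver-1 NIKsh#1 and from 79.3 to 55.7 in Maver-1 NIKsh#2. In the NTC cultures it went from 46.4 to 55.4 in Z-138 and from 77.2 to 132.7 in Maver-1. All 4 NIKsh changes lay below both NTC changes, a difference of -0.92 (exact permutation p = 0.0667, two-sided, the smallest this design allows). Flipping the signs of the 4 NIKsh pairs gave an exact p of 0.125, also the smallest possible, and in limma the NIKsh change of MAP3K14 did not pass (-0.42 ± 0.18, adjusted p = 0.529). The signal left with doxycycline was 0.603 to 0.946 of that without it.

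The main comparison asked which genes respond to doxycycline in the 4 NIKsh cultures. A set of 5 genes fell and 0 rose (limma, adjusted p under 0.05), each with the same sign in 4 of 4 cultures. ADTRP, a membrane hydrolase of fatty acid esters (chromosome 6), fell by 1.81 ± 0.18 on the log2 scale (adjusted p = 0.0097), while its NTC values were 0.27 and 0.30. NAV2, a cytoskeletal protein of neurite growth (chromosome 11), fell by 1.46 ± 0.15 (adjusted p = 0.0097). CXorf65 (chromosome X) fell by 1.43 ± 0.18 (adjusted p = 0.0385). HVCN1, the voltage-gated proton channel of B cells and phagocytes (chromosome 12), fell by 1.18 ± 0.14 (adjusted p = 0.0279), and IL21R, the receptor of interleukin 21 (chromosome 16), fell by 1.17 ± 0.16 (adjusted p = 0.0427). At an unadjusted p under 0.05 there were 1037 genes, where chance gives 577. The count of 5 was not stable, as limma called 0 genes without Z-138 NIKsh#1 (523 at an unadjusted p under 0.05) and 0 without Maver-1 NIKsh#1 (1048). It called 2 without Z-138 NIKsh#2, 3 without Z-138 NTC and 3 without Maver-1 NTC. Leaving out a culture also costs a residual degree of freedom, and lost precision was not separated from dependence on a culture. The 5 genes themselves lay between -2.13 and -0.96 in the 4 NIKsh cultures. Without the culture block 135 genes passed, with culture as a random block 197 and with array weights 18.

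Below these, 7 more genes were lower in all 4 NIKsh cultures by at least 1.5-fold and filled the remaining places, without passing the test. CELSR1, a cadherin of planar cell polarity, had a change of -1.73 ± 0.24 (adjusted p = 0.0537). COL1A1 (a type I collagen chain) at -1.17, CTSH (the lysosomal protease cathepsin H) at -0.86, CLEC7A (the glucan receptor dectin-1) at -1.73, L1CAM (an adhesion molecule) at -1.34, CHRNA6 (a nicotinic receptor subunit) at -1.44 and CSF2RB (the shared signalling chain of the GM-CSF receptor) at -1.35 all had an adjusted p of 0.0863. In the other direction, TLR10, a Toll-like receptor of B cells, had a value of 1.32 ± 0.25 (adjusted p = 0.156) and LDLRAD3, an LDL receptor family protein, 0.78 ± 0.16 (adjusted p = 0.179). LDLRAD3 had NTC values of -0.69 and -0.70. The other genes with positive values were DACT1 (a regulator of Wnt signalling) at 1.02, FAM171A1 at 1.22, CETP (cholesteryl ester transfer protein) at 1.03, PIGR (the polymeric immunoglobulin receptor) at 0.92, GAREM1 (an adaptor of growth factor signalling) at 1.06, and the long non-coding RNAs LINC02532 at 0.84 and PWAR6 at 0.72. GAREM1 was also at 0.97 and 0.63 in the NTC cultures, and FAM171A1 at 1.51 in Z-138 NTC. In all, 31 genes were at least 1.5-fold apart the same way in all 4 NIKsh cultures, 9 higher and 22 lower. The other 7 sign patterns gave at most 8 genes (median 2), and 7 of the 9 and 21 of the 22 lay beyond both NTC values. The count was 18 with averaged probe sets and 53 without the filter.

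**Figure D2:**
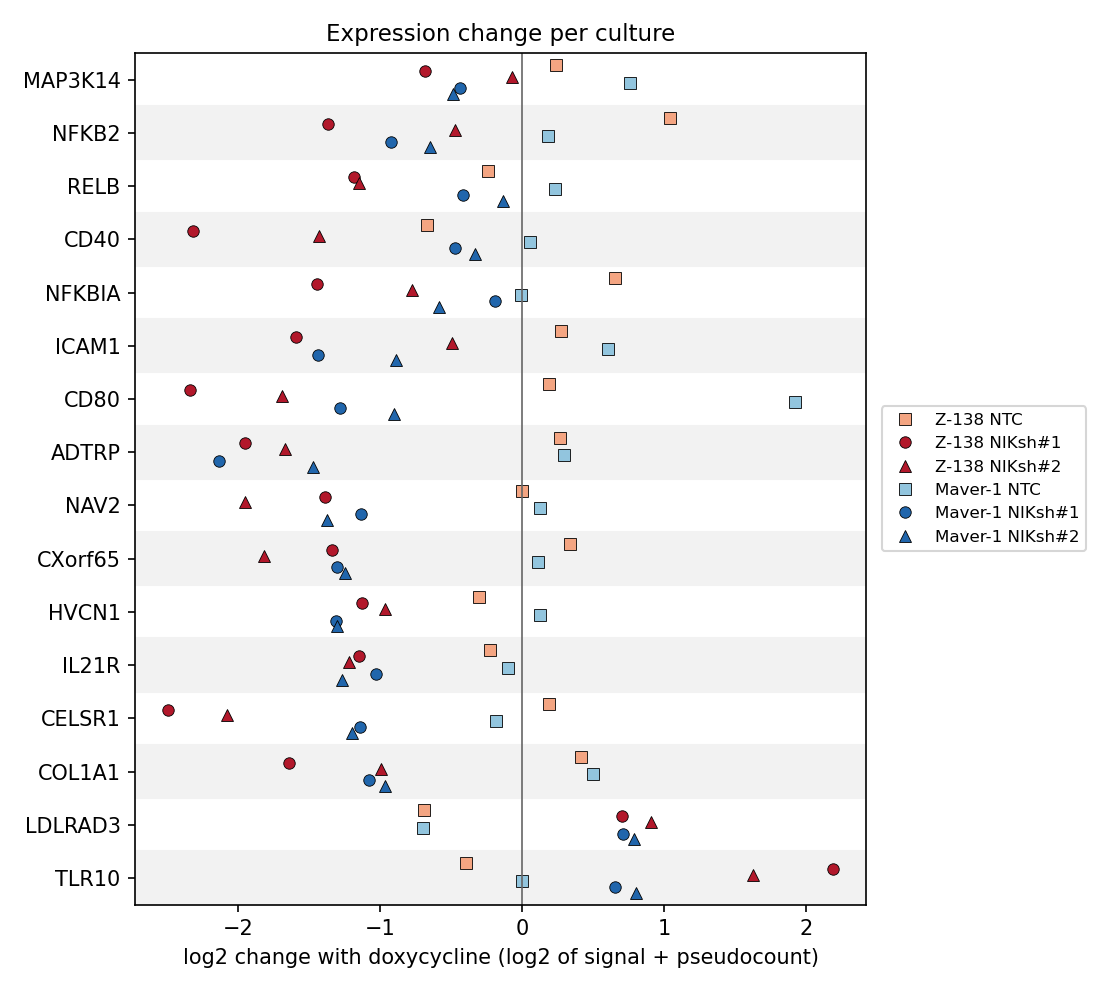
Log2 doxycycline change (horizontal axis, log2 of signal plus pseudocount) of 16 genes in each of the 6 cultures, 1 point per culture, by line (colour) and construct (shape). For ADTRP, NAV2, CXorf65, HVCN1 and IL21R the 4 NIKsh points lie between -2.13 and -0.96, and the NTC points between -0.31 and 0.34. CD80, ICAM1, NFKB2, RELB, CD40 and NFKBIA are members of the NF-kB lists.

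As a group, NF-kB target genes fell in the NIKsh cultures, with a median change of -0.30 over 44 genes, 34 of them negative (camera adjusted p = 6.14e-08). The adjusted p = 0.186 with an estimated correlation, and 0.0604 with fry. Over all genes, 0 members passed limma, and 10 passed when adjusted over the list alone. Among these were CD80, a costimulatory ligand for T cells, at -1.55 ± 0.32 (with untreated mean signals of 74.27 in Z-138 and 5.567 in Maver-1, the latter under the filter signal of 12.55), PLEK, a cytoskeletal protein kinase C substrate, at -1.28 ± 0.26, ICAM1, an adhesion molecule for leukocytes, at -1.10 ± 0.20, and NFKBIA, the inhibitor of canonical NF-kB, at -0.75 ± 0.20. The others were CD40, NFKB2, RELB, CCR7 (-0.56), CFLAR (-0.72) and NFKBIE (-0.77). By culture the list's median was -0.36, -0.13, -0.22 and -0.23 in Z-138 NIKsh#1, Z-138 NIKsh#2, Maver-1 NIKsh#1 and Maver-1 NIKsh#2, and 0.11 and 0.05 in Z-138 NTC and Maver-1 NTC (exact p = 0.0667, two-sided, the smallest possible).

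Alternative NF-kB pathway components were 10 genes, among them MAP3K14 (-0.42), the target of the hairpins. They had a median of -0.06, a mean of -0.28 and 8 negative values, and fell by camera (adjusted p = 0.0208). This list's adjusted p = 0.266 with an estimated correlation. No member passed over all genes in limma (count 0, with 4 at an unadjusted p under 0.05), and 3 passed when adjusted over the list alone. These were CD40, the B cell receptor for CD40 ligand, at -1.14 ± 0.30 (also at -0.67 in Z-138 NTC), NFKB2, the precursor that NIK signalling processes, at -0.85 ± 0.20, and RELB, the partner of processed NFKB2, at -0.72 ± 0.22. All 3 also stand in the NF-kB target list, so these lists are not separate evidence. CHUK, the kinase that NIK activates, stood at -0.03 ± 0.13, BIRC2 (the ubiquitin ligase cIAP1) at -0.04 ± 0.15, and the BAFF and APRIL receptors TNFRSF13B, TNFRSF13C and TNFRSF17 at 0.28 ± 0.24, 0.00 ± 0.47 and -0.09 ± 0.09. TRAF3 was at -0.185 and -0.28 in the Z-138 NIKsh cultures, and its mean over both lines, 0.21 ± 0.25, like its share in the list's mean, includes Maver-1 values at the floor of the array (untreated mean signal 1.83). The canonical NF-kB pathway components, 21 genes, had a median of -0.07 and fell by camera (adjusted p = 0.0327), with adjusted p = 0.309 with an estimated correlation. Adjusted over the list alone, 3 passed, against 0 over all genes: NFKBIA, NFKBIE (another NF-kB inhibitor) and CYLD, a deubiquitinase that restrains NF-kB, at -0.71 ± 0.16. Of these, NFKBIA and NFKBIE are in the NF-kB target list as well.

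MHC class II genes, which present antigen to helper T cells, fell with a median of -0.36 over 16 genes, 15 of them negative (camera adjusted p = 2.17e-14). The adjusted p = 0.186 with an estimated correlation. Adjusted over the list alone, 13 passed, and 0 passed over all genes in limma. HLA-DQA1 was at -0.72 ± 0.18, HLA-DOB at -0.61 ± 0.22, RFXANK, a subunit of the factor that binds class II promoters, at -0.54 ± 0.15, HLA-DMA, which helps load peptides, at -0.49 ± 0.11 and CIITA, the class II transactivator, at -0.39 ± 0.13 (0.033 with averaged probe sets). The values of CD74, HLA-DRB1 and RFX5 were smaller, at -0.19 each. The median per culture was -0.64, -0.24, -0.31 and -0.23 in the NIKsh cultures, in the order given for the NF-kB targets, and 0.08 and 0.10 in NTC (exact p = 0.0667, two-sided, the smallest possible). MHC class I genes, 18 in number, had a median of -0.15 with 14 negative and fell by camera (adjusted p = 0.00604), with adjusted p = 0.248 with an estimated correlation. Here 0 members passed over all genes and 0 adjusted over the list alone, with HLA-F at -0.35 and PSMB9, an immunoproteasome subunit, at -0.33.

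**Figure D3:**
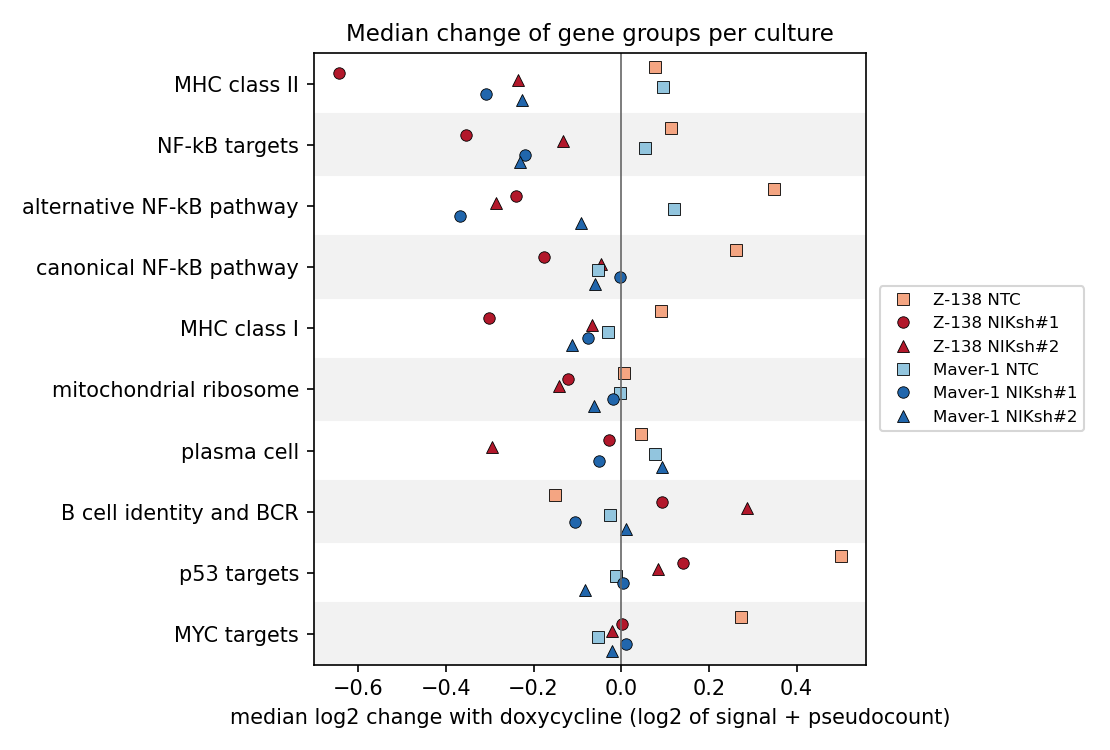
Median log2 doxycycline change (horizontal axis, log2 of signal plus pseudocount) of 10 gene lists in each of the 6 cultures, 1 point per culture, by line (colour) and construct (shape). The 4 NIKsh points of MHC class II lie between -0.64 and -0.23 and the NTC points at 0.08 and 0.10.

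A further 6 lists fell by camera in the NIKsh cultures, and none passed with an estimated correlation or fry. Genes of the mitochondrial ribosome had a median of -0.08, with 36 of 42 negative (adjusted p = 1.1e-05), and adjusted p = 0.248 with an estimated correlation, and 0 genes passed over all genes or adjusted over the list alone. Plasma cell genes, 20 in number, had a median of -0.05 (adjusted p = 0.0157; adjusted p = 0.351 with an estimated correlation), with 2 passing when adjusted over the list alone and 0 over all genes. The 2 genes were ELL2, an elongation factor used in immunoglobulin secretion, at -1.57 ± 0.38 and MZB1, a chaperone of antibody assembly, at -0.77 ± 0.19, which was also at -0.79 in Z-138 NTC. Chemokine and homing genes had a median of -0.21 over 14 genes (adjusted p = 0.0362; adjusted p = 0.309 with an estimated correlation), and CCR7, which guides lymphocytes into lymph nodes, at -0.56 ± 0.13 was the 1 gene that passed when adjusted over the list alone, against 0 over all genes. In Z-138 CCR7 was at -0.522 in NTC and at -0.476 in both NIKsh cultures, and in Maver-1 at -0.03 in NTC and -0.467 and -0.811 in NIKsh. Apoptosis genes had a median of -0.16 over 24 (adjusted p = 0.0362; adjusted p = 0.266 with an estimated correlation). Adjusted over the list alone, CFLAR at -0.72 ± 0.13 and BCL2 at -0.29 ± 0.07, both of which restrain cell death, passed, against 0 over all genes. S phase genes had a median of -0.06 over 39 (adjusted p = 0.0224) and G2/M genes -0.04 over 40 (adjusted p = 0.0212), each with adjusted p = 0.604 with an estimated correlation and 0 genes passing either way. By culture only mitochondrial ribosome and chemokine genes had negative medians in all 4 NIKsh cultures. Chemokine genes were at -0.293 in Z-138 NTC, against -0.116 and -0.025 in Z-138 NIKsh. Positive medians were 0.144 for S phase in Z-138 NIKsh#2 and 0.092 for plasma cell genes in Maver-1 NIKsh#2. Others were 0.033 for G2/M in Maver-1 NIKsh#1 and 0.02 for apoptosis in Z-138 NIKsh#1. With the filter at the 75th percentile 4 lists passed in place of 11.

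Of the 25 lists, 14 did not pass camera in this comparison. Their medians and adjusted p were -0.03 for respiratory chain (0.0573), -0.27 for monocyte markers (0.0695), 0.08 for B cell identity (0.0888), 0.02 for histone and RNA-interference genes (0.134), -0.20 for fibroblast, epithelial and endothelial markers (0.134), -0.33 for T and NK cell markers (0.134) and -0.04 for glycolysis (0.208). The rest were MYC targets at -0.04 (0.358), cholesterol synthesis at -0.01 (0.533), p53 targets at 0.05, mantle cell lymphoma features at 0.02 and endoplasmic reticulum chaperones at -0.01 (0.562 each), the ATF4 stress response at -0.02 (0.62) and interferon response at 0.05 (0.788). For mantle cell lymphoma features the mean was -0.01 and the test pointed down. Adjusted over the list alone, single members of these lists passed, against 0 over all genes: VLDLR, a lipoprotein receptor, at 0.66, ROR1, a receptor tyrosine kinase, at 0.66, PFKFB3, a regulator of glycolysis, at 0.46, ALDOC (aldolase C) at -0.74, BCL2, COL1A1, and the T cell genes CD7 at -0.81 and LCK at -1.01.

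The NTC cultures asked what doxycycline and hairpin induction do without the MAP3K14 hairpins. In limma 0 genes passed over 2 cultures (387 at an unadjusted p under 0.05, where chance gives 577). Genes of the p53 pathway, which halt the cell cycle or start cell death after damage, rose as a list by camera, with a median of 0.28 and 21 of 25 positive (adjusted p = 0.00123, and adjusted p = 0.774 with an estimated correlation). Here 0 members passed over all genes or adjusted over the list alone, FAS, a death receptor, stood at 1.04 ± 0.43 and BAX, a cell death effector, at 0.44 ± 0.14. By culture the list's median was 0.50 in Z-138 NTC and -0.01 in Maver-1 NTC, and Z-138 NTC was the culture whose ACTB ratio went from 2.33 to 6.34. MYC target and ribosome biogenesis genes also rose by camera, with a median of 0.13 and 28 of 34 positive (adjusted p = 0.0256, and adjusted p = 0.774 with an estimated correlation), and the median was 0.27 in Z-138 NTC and -0.05 in Maver-1 NTC. Single genes with the same sign in both cultures, none of which passed (adjusted p = 0.895 each), included ACTA2 (smooth muscle actin) at 1.68, RAG2, of the V(D)J recombinase, at 1.29, JDP2 at 1.20, HID1 at 1.31, METAP1D at 0.69 and LINC02728 at 0.96. Lower values were those of APOBEC3B, a cytidine deaminase, at -1.01, TVP23B at -0.74, HMMR-AS1 at -1.03, REEP1 at -1.10, TRIM31 at -1.14 and TBC1D9 at -0.69.

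To set the knockdown against induction as such, the NIKsh effect was compared with the NTC effect. In limma 0 genes passed (627 at an unadjusted p under 0.05, where chance gives 577), and 10 lists passed camera, 9 lower and 1 higher in NIKsh. MHC class II genes were lower by camera, with a median of -0.47 and 15 of 16 negative (adjusted p = 3.88e-10, and adjusted p = 0.289 with an estimated correlation). For this list 5 genes passed when adjusted over the list alone and 0 over all genes, among them CIITA at -0.85 ± 0.23 and HLA-DOA, which tunes peptide loading, at -0.81 ± 0.18. NF-kB target genes had a median of -0.28, with 35 of 44 negative (adjusted p = 2.93e-05, and adjusted p = 0.289 with an estimated correlation). Adjusted over the list alone, 5 passed, against 0 over all genes: CD80 at -2.61 ± 0.55 (from NTC changes of 0.19 in Z-138 and 1.92 in Maver-1, the latter from a signal of 1.3 without doxycycline), ICAM1 at -1.54 ± 0.35, NFKB2 at -1.47 ± 0.34, CFLAR at -0.96 ± 0.23 and, with the opposite sign, the activation marker CD69 at 1.06 ± 0.21. Alternative NF-kB components, which include MAP3K14, had a median of -0.42 (adjusted p = 0.0114, and adjusted p = 0.289 with an estimated correlation). Of them NFKB2 was the 1 gene that passed when adjusted over the list alone.

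In the same comparison the B cell identity list had a median of 0.19, with 23 of 33 positive (camera adjusted p = 0.0136, and adjusted p = 0.507 with an estimated correlation), with PAX5, a factor that maintains B cell fate, at 0.98 ± 0.31 and CD72, a co-receptor of B cells, at 0.89 ± 0.29, while 0 members passed over all genes or adjusted over the list alone. By culture the B cell median was 0.09 and 0.29 in Z-138 NIKsh and -0.15 in Z-138 NTC, but -0.11 and 0.01 in Maver-1 NIKsh and -0.03 in Maver-1 NTC (exact p = 0.333). Mitochondrial ribosome genes (median -0.14 over 42) and MYC targets (-0.12 over 34) each had an adjusted p of 0.0136, with adjusted p = 0.477 and 0.521 with an estimated correlation. Fibroblast, epithelial and endothelial markers had a median of -0.48 over 8 genes (adjusted p = 0.0207, and adjusted p = 0.289 with an estimated correlation), of which COL1A1 at -1.63 ± 0.31 passed when adjusted over the list alone. Glycolysis (median -0.21), p53 targets (-0.16) and plasma cell genes (-0.19) each had an adjusted p of 0.0219, with adjusted p = 0.477, 0.527 and 0.495 with an estimated correlation. For p53 targets the medians were 0.14, 0.08, 0.01 and -0.08 in the NIKsh cultures, against 0.50 in Z-138 NTC and -0.01 in Maver-1 NTC. Glycolysis (0.21 and -0.04 in NTC) and MYC targets (0.27 and -0.05) were likewise high in Z-138 NTC, whose ACTB ratio went from 2.33 to 6.34, while their NIKsh medians lay between -0.10 and 0.03. Single genes with the same sign in all 4 NIKsh pairs, none of which passed, were led by ADTRP at -2.09 ± 0.31 (adjusted p = 0.559), LDLRAD3 at 1.47 ± 0.27 and PIGR at 1.97 ± 0.38 (0.623 each). NAV2 at -1.52, CXorf65 at -1.65, L1CAM at -1.82 and CSF2RB at -1.82 also had an adjusted p of 0.623, and EPB41L4B, of the cortical cytoskeleton, was at -2.90 and GGTLC1 at -1.49 (0.876 each). MAP3K14 was at -0.92 ± 0.32 (adjusted p = 0.879). With limma, 23 genes passed without the culture block, 33 with culture as a random block and 32 with effects averaged over the lines.

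The lines carry different lesions of the NIK pathway, so the NIKsh effect was compared between them as Z-138 minus Maver-1, over 2 cultures each. In limma 14 genes passed, 6 with a higher and 8 with a lower value in Z-138 (992 at an unadjusted p under 0.05, where chance gives 577). Of these, 6 were named by the rule. KLHL14, an adaptor protein of B cell receptor turnover, had a difference of 1.83 ± 0.23 (adjusted p = 0.0323) from changes of 1.94 in Z-138 and 0.11 in Maver-1. UNC13C, a vesicle priming protein, had -2.66 ± 0.37 (adjusted p = 0.0474), ELL2 -2.20 ± 0.28, ENPP2, the enzyme autotaxin, -1.60 ± 0.20, PLEK -1.50 ± 0.19 (0.0323 each) and ABCG1, a cholesterol exporter, -1.45 ± 0.20 (adjusted p = 0.046). In all 6 the larger change was the one in Z-138. UNC13C without doxycycline had a signal of 102 in Maver-1 NIKsh#2 against 801 and 714 in the other Maver-1 cultures.

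The other 8, chosen after their values were seen, were AFF3, a nuclear factor, at 3.04 ± 0.26 (adjusted p = 0.00495), NIBAN3 at 2.20 ± 0.26, the G protein regulators RGS1 at 2.06 ± 0.19 and RGS2 at 1.88 ± 0.15, RPS24, a ribosomal protein, at 0.54 ± 0.08 (adjusted p = 0.0492), AQP3, a water and glycerol channel, at -2.18 ± 0.30, the cytokine IL10 at -3.27 ± 0.44 and SIM1, a transcription factor, at -4.04 ± 0.45. IL10 and SIM1 had untreated mean signals of 0.8 and 0.6 in Maver-1, at the floor of the array, against 63.9 and 58.5 in Z-138. By camera, plasma cell genes had a lower response in Z-138 (median difference -0.16, adjusted p = 0.000507), MHC class II genes a lower one (-0.22, adjusted p = 0.00411) and B cell identity genes a higher one (0.28, adjusted p = 0.00221). Each of the 3 had adjusted p = 0.723 with an estimated correlation. For NIKsh#1 and NIKsh#2 the plasma cell medians were -0.027 and -0.295 in Z-138, and -0.05 and 0.092 in Maver-1. Those of MHC class II were -0.644 and -0.236 in Z-138, and -0.309 and -0.227 in Maver-1. By these medians the lines differed in NIKsh#2 for plasma cell genes and in NIKsh#1 for MHC class II, and hardly in the other hairpin. Adjusted over the list alone, ELL2 and MZB1 (-0.88) passed among plasma cell genes, BANK1, a B cell scaffold, at 1.75 and MS4A1, the surface antigen CD20, at 0.33 among B cell genes, and 0 among MHC class II genes, against 1, 0 and 0 over all genes. NF-kB targets had a median of -0.10 (adjusted p = 0.128) with 3 passing over all genes and 5 adjusted over the list alone, among them TNFAIP3, an inhibitor of NF-kB, at -1.45 ± 0.22. The ACTB ratio differed between the lines in the same pairs (2.86 to 4.62 and 2.92 to 5.09 in Z-138, 4.68 to 4.32 and 3.66 to 3.8 in Maver-1). With that ratio as a covariate limma called 0 genes (290 at an unadjusted p under 0.05), the median size going from 2.12 to 1.96 and the median standard error from 0.24 to 1.51 at 1 residual degree of freedom. Of the 14, 12 kept their sign, and ELL2 and NIBAN3 were at 0.37 ± 1.71 and -0.07 ± 1.48. Without the variance trend limma called 0 (941) and with averaged probe sets 1, and leaving out Z-138 NIKsh#1 gave 423, Z-138 NIKsh#2 84, Maver-1 NIKsh#1 45 and Maver-1 NIKsh#2 69, where the 1 NIKsh culture left in a line is assumed to vary like the others.

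**Figure D4:**
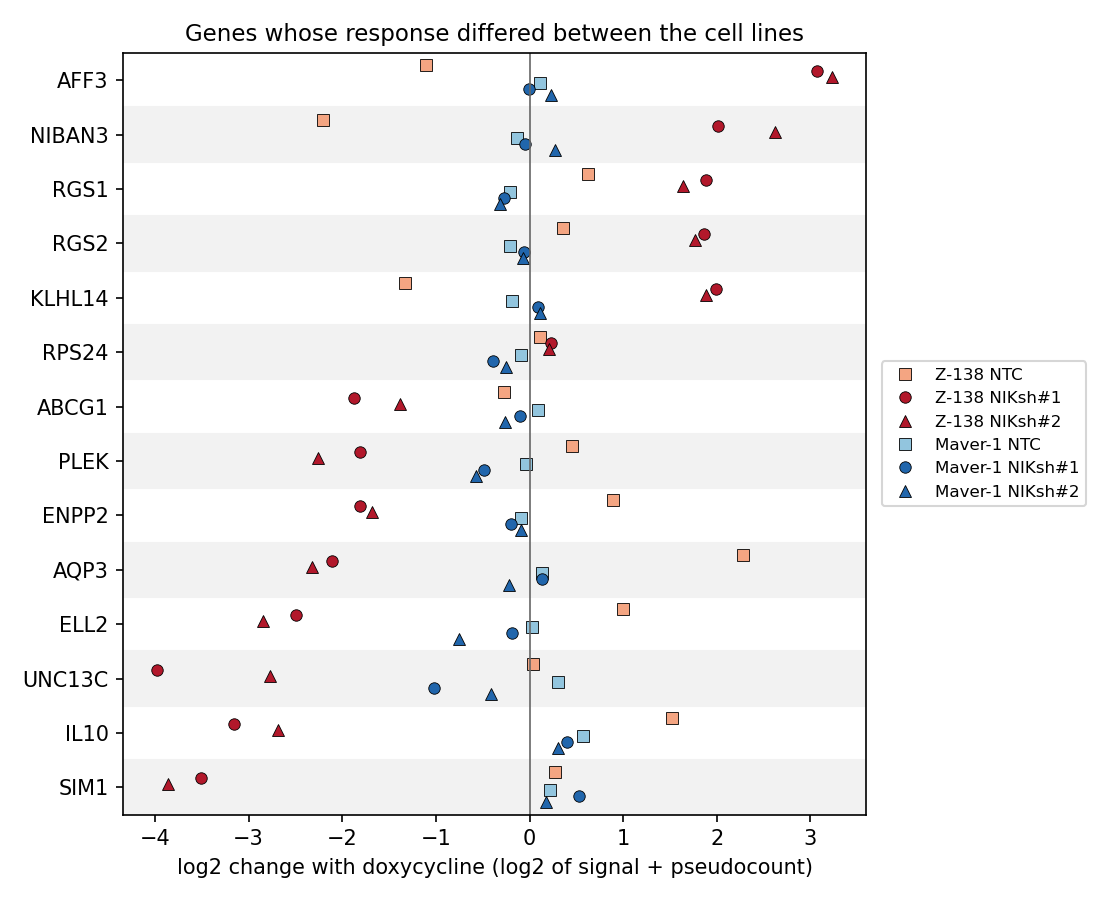
Log2 doxycycline change (horizontal axis, log2 of signal plus pseudocount) of the 14 genes whose NIKsh response differed between the lines, 1 point for each of the 6 cultures, by line (colour) and construct (shape). AFF3 lies at 3.07 and 3.23 in the Z-138 NIKsh cultures and at -0.01 and 0.23 in the Maver-1 ones.

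The hairpins target the same gene, and limma called 0 genes whose response differed between NIKsh#1 and NIKsh#2 (202 at an unadjusted p under 0.05). MAP3K14 differed by -0.28 ± 0.39, NAV2 by 0.40 ± 0.30, ADTRP by -0.47 ± 0.36, COL1A1 by -0.38 ± 0.37 and CETP by 0.72 ± 0.38, each less than 2 standard errors (adjusted p = 1 for all). TNFRSF13C differed by -2.23 ± 0.68 with the same adjusted p. Taken alone over 2 cultures, NIKsh#1 gave 0 genes and NIKsh#2 gave 0 genes in limma, with 488 and 612 at an unadjusted p under 0.05. Their effects, each averaged over the lines, correlated across genes at 0.428 (genes are not independent replicates). By culture NIKsh#1 and NIKsh#2 correlated at 0.365 in Z-138 and 0.149 in Maver-1. The same hairpin correlated between lines at 0.166 for NIKsh#1 and 0.014 for NIKsh#2. With Z-138 NTC, Z-138 NIKsh#1 correlated at -0.062 and Z-138 NIKsh#2 at 0.278.

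The untreated lines differed at many genes. In limma 6956 of 11548 genes passed between 3 Z-138 and 3 Maver-1 cultures, 2939 higher in Z-138 and 4017 higher in Maver-1. The ACTB ratio of these untreated arrays was 2.33, 2.86 and 2.92 in Z-138 and 6.88, 4.68 and 3.66 in Maver-1. That of GAPDH ran from 1.15 to 1.3 in Z-138 and from 1.54 to 2.39 in Maver-1. As the lines did not overlap in either ratio, the share of RNA signal along transcripts in this count cannot be told. TRAF3 was higher in Z-138 by 6.12 ± 0.27 (adjusted p = 7.21e-10), with mean signals of 317.2 and 1.83, the latter at the floor of the array in the line labelled with its deletion. Among the genes higher in Z-138 were LMO3, a transcriptional co-factor, at 8.10 ± 0.17, APP, the amyloid precursor, at 8.01, ROBO1, a guidance receptor, at 7.88, FGF9, a growth factor, at 7.87, NIBAN1 at 7.85 and IGKC, the kappa light chain constant region, at 7.01. Among those higher in Maver-1 were UCHL1, a ubiquitin hydrolase, at -8.70 ± 0.16, BCL2L11, the cell death inducer BIM, at -8.61 ± 0.24, EPDR1 at -8.12, BCOR, a corepressor, at -7.89, TCL1A, a co-activator of AKT, at -7.77, S100A10 at -7.55 and CD44, a hyaluronan receptor, at -7.12. The remaining named genes were SCML1, IGF2BP1, FABP6, NUDT11, C9orf72 and AMOTL1, from 6.14 to 6.95, and PKP2, IMPACT, GPAT2, TRBC1 and MGST1, from -7.50 to -7.06. Where 1 line is at the floor these sizes depend on the pseudocount.

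Of the alternative NF-kB components without doxycycline, 7 of 10 passed. MAP3K14 was lower in Z-138 by a log2 difference of -0.64 ± 0.16 (adjusted p = 0.00401), CD40 by -1.13 ± 0.15, NFKB2 by -0.61 ± 0.14, BIRC2 by -0.59 ± 0.13 and CHUK by -0.55 ± 0.11, while TRAF3 and TNFRSF17 (0.37 ± 0.07) were higher. RELB at 0.42 ± 0.18 (adjusted p = 0.0566), TNFRSF13B at -0.13 ± 0.29 and TNFRSF13C at -0.08 ± 0.33 did not pass. As a list they had a median of -0.34 and a mean of 0.32, and camera pointed down without passing (adjusted p = 0.907).

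The last comparison checked for effects of the hairpins without doxycycline. In limma 0 genes passed between the 4 NIKsh and 2 NTC untreated cultures (552 at an unadjusted p under 0.05, where chance gives 577). MAP3K14 differed by 0.15 ± 0.17 (adjusted p = 0.989). Among genes at least 1.5-fold apart with all 4 NIKsh levels on the same side of both NTC levels, those with the smallest p included MAP2K2, a kinase of the MAP kinase cascade, at 0.68 ± 0.14, LINC00996 at 0.68 and PAGR1 at -0.59 (0.901 each), TLR9, a receptor for DNA, at 0.88 and GSS, glutathione synthetase, at -0.62. Without Maver-1 NTC 108 genes passed and without Z-138 NTC 11, where a single NTC culture is assumed to vary like the others.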

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

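The covariate for the ACTB ratio and the test of IL10 and SIM1 against the array floor were chosen after the results were seen. The other tests in this part address patterns already seen, and their predictions were written before the outcomes of the tests themselves. The results below are differences between the lines, Z-138 minus Maver-1, in the doxycycline change of NIKsh cultures by limma for genes and camera for lists, and in the spread of all pairs, which has no test.

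For 14 genes the change differed, by 3.04 for AFF3, 2.20 for NIBAN3, 2.06 for RGS1, 1.88 for RGS2, 1.83 for KLHL14, 0.54 for RPS24, -1.45 for ABCG1, -1.50 for PLEK, -1.60 for ENPP2, -2.18 for AQP3, -2.20 for ELL2, -2.66 for UNC13C, -3.27 for IL10 and -4.04 for SIM1. A difference in 3' to 5' RNA signal would move the NTC pairs the same way, if nothing else moved them. The ACTB ratio there went from 2.33 to 6.34 in Z-138 and from 6.88 to 4.43 in Maver-1. But the NTC line difference, signed by each gene's NIKsh difference, had a median of -0.716 (quartiles -1.10 and 0.25, against 2.12 in NIKsh). It pointed the other way in 9 of 14 genes. Z-138 NTC itself was at 2.285 for AQP3 and -2.207 for NIBAN3, and other causes of such changes cannot be separated. With 1 NTC pair per line, this argues only weakly against RNA signal as the common cause. With that ratio as a covariate limma called 0 genes (290 at an unadjusted p under 0.05), as the median standard error went from 0.24 to 1.51 at 1 residual degree of freedom and the median size from 2.12 to 1.96, with 12 of 14 keeping their sign, so precision was lost, and whether the moves of single estimates (ELL2 from -2.20 to 0.37 ± 1.71, NIBAN3 from 2.20 to -0.07 ± 1.48, AQP3 from -2.18 to -0.60 ± 2.22, PLEK from -1.50 to -0.30 ± 1.14, RPS24 from 0.54 to 0.15 ± 0.41, UNC13C from -2.66 to -7.08 ± 1.55) go beyond that was not tested. Signal near the floor in the line with the smaller response held for 14.3% of the genes, IL10 and SIM1, whose untreated means in Maver-1 were 0.8 at most, so their differences may reflect that only Z-138 expresses them, while the other 12 had untreated mean signals of at least 349.3 in the line with the smaller response. A response that differs with the TRAF2 and TRAF3 lesions, or with other features of the lines, stays open and was not tested, and the selection of 14 genes depends on single cultures (423 without Z-138 NIKsh#1, where the lone Z-138 NIKsh culture is assumed to vary like the others).

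The pairs of Z-138 also spread more than those of Maver-1, with SDs over genes of 0.541, 0.46 and 0.513 against 0.264, 0.301 and 0.351. A signature of 3' to 5' signal, the untreated Maver-1 NTC array against the untreated Maver-1 NIKsh arrays, correlated across genes, which are not independent replicates, at 0.306 with the Z-138 NTC change, -0.001 with Z-138 NIKsh#1 and 0.154 with Z-138 NIKsh#2. The largest SD was that of Z-138 NTC, which holds no MAP3K14 hairpin. It had 807 genes at least 2-fold apart, against 488 in Z-138 NIKsh#1 and 686 in Z-138 NIKsh#2. A stronger response to the knockdown alone therefore does not account for the wider spread in Z-138. RNA signal along transcripts and a stronger response of Z-138 to doxycycline or hairpin induction cannot be told apart here. The signature rests on 1 array and holds whatever else differed between those cultures.

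By camera with the preset correlation, the median difference was 0.28 for B cell identity genes (mean of medians 0.19 in Z-138 and -0.05 in Maver-1). MHC class II genes differed by a median of -0.22 (-0.44 and -0.27). Their medians in Z-138 and Maver-1 were -0.644 and -0.309 with NIKsh#1, but -0.236 and -0.227 with NIKsh#2. Plasma cell genes differed by -0.16 (-0.16 and 0.02). Here the medians were -0.027 and -0.05 with NIKsh#1, and -0.295 and 0.092 with NIKsh#2. The ACTB ratio rose in these Z-138 pairs and was nearly flat in the Maver-1 ones, and its part in the list differences was not tested. That of GAPDH rose in Z-138 NIKsh#2 (1.15 to 1.83) but hardly in Z-138 NIKsh#1 (1.3 to 1.36). All 3 lists had adjusted p = 0.723 with an estimated correlation.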

How the results depend on the processing

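The ACTB covariate, alone or with an estimated correlation, and the pseudocount of 16 with a signal minimum of 50 were chosen after the results were seen, and all other alternatives before. The counts of 0 for NTC and for the hairpin difference stayed at 0 in limma in all 19 alternatives, and MAP3K14 kept its sign and its side of the threshold in 18 (-0.535 to -0.333 leaving out a culture, -0.475 to -0.344 otherwise), with no value at the 75th percentile filter, which removes it. The untreated line count ran from 4770 to 7279, apart from 12543 probe sets tested singly, which is more features. Signal over background limits genes near the floor, and the 4 or 2 cultures per effect limit the rest. Where no cause is given below, the cause was not tested.

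How culture was modelled moved the NIKsh count most. It was 5 with a fixed block, 135 without a replicate block and 197 with culture as a random block (correlation 0.104). For NIKsh against NTC these gave 23 and 33, and 32 genes with effects averaged over the lines. The NIKsh count was 3 without the filter, 2 at the 75th percentile (7631 genes), 3 with averaged and 2 with separate probe sets, 3 without the variance trend and 18 with array weights. Leaving out a culture gave 0 to 5. The line difference gave 9 genes at pseudocount 1, 9 without the filter, 8 at the 75th percentile, 1 with averaged and 3 with separate probe sets, 0 without the trend and 0 with the ACTB covariate, which leaves 1 residual degree of freedom. Leaving out a culture gave 9 to 423, the lowest without Z-138 NTC and the highest without Z-138 NIKsh#1. The untreated NIKsh and NTC comparison gave 0 to 108, and NIKsh against NTC 0 to 0. A culture left alone in its arm is assumed to vary like the others.

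For lists in NIKsh cultures 4 passed at the 75th percentile, which measures fewer genes, 0 with an estimated correlation and 0 with fry, and 8 to 12 leaving out a culture. Against NTC 6 passed with quantile normalization, 5 at the 75th percentile, 0 with an estimated correlation and 0 with fry, and 4 to 14 leaving out a culture. The set tests leave the medians as they were and end the calls. With an estimated correlation camera also rests on the few residual degrees of freedom of the model. A lost call can thus reflect low power as well as correlated genes. NF-kB targets at -0.302 had an adjusted p of 0.186 with an estimated correlation and 0.0604 with fry, and MHC class II at -0.364 the same p-values. With the ACTB covariate and an estimated correlation NF-kB targets were -0.292 (adjusted p = 0.399). Against NTC they were -0.281 (0.289 and 0.14) and -0.466 (0.289 and 0.143). Genes at least 1.5-fold apart in all 4 NIKsh cultures numbered 18 at 4 times the pseudocount, 53 without the filter, 8 at the 75th percentile, 18 with averaged probe sets, 14 at pseudocount 16 and 6 at 2-fold. Leaving out a culture gave 31 to 103, as fewer pairs must match. With the NTC pair subtracted it was 103, 53 higher and 50 lower in place of 9 and 22, where the shared NTC pair also raised the highest other sign pattern to 37.

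Single genes whose sign turned had not passed over all genes, apart from ELL2 and NIBAN3 in the line difference. CIITA in NIKsh and PECAM1 and LCK in the line difference had passed adjusted over their list alone. In NIKsh cultures TRAF3, at the floor in Maver-1, was -0.004 at 4 times the pseudocount, -0.069 with averaged probe sets and -0.027 at pseudocount 16. TNFRSF13C was 0.072 at 4 times the pseudocount, CIITA 0.033 with averaged probe sets and BIRC2 0.012 with array weights. Against NTC TRAF3 was -0.268, -0.366 and -0.306 under its 3 settings, and TNFRSF13B -0.102 with array weights. In the line difference PIGR was -0.071 and GAREM1 -0.042 with averaged probe sets, and MAP3K14 -0.017 with array weights. Untreated TNFRSF13C was 0.116 with array weights. With the ACTB covariate the line difference was -0.021 for DACT1, -0.11 for HVCN1, 0.366 for ELL2, 2.795 for EPB41L4B, -0.973 for MAP3K14, 0.071 for CHUK, 1.372 for BIRC2, -3.6 for TNFRSF13B, -11.497 for TNFRSF13C, 1.401 for TNFRSF17, 1.77 for PECAM1, 1.608 for LCK and -0.067 for NIBAN3.

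Leaving out a culture, ranges that crossed 0 in NIKsh were -0.438 to 0.645 for TNFRSF13C, -0.06 to 0.481 for TNFRSF13B, -0.068 to 0.001 for CHUK, -0.123 to 0.05 for BIRC2 and -0.143 to 0.017 for TNFRSF17. Against NTC they were -0.504 to 0.617 for TRAF3, -1.431 to 0.144 for TNFRSF13C, -0.271 to 0.27 for TNFRSF13B, -0.536 to 0.176 for CHUK, -0.491 to 0.159 for BIRC2, -0.391 to 0.007 for TNFRSF17 and -0.286 to 1.251 for FAM171A1. In the line difference they were -0.219 to 0.387 for MAP3K14, -0.582 to 0.314 for NFKB2, -0.409 to 2.448 for TNFRSF13C and -0.386 to 0.083 for TNFRSF17, and untreated -0.366 to 0.302 for TNFRSF13C and -0.393 to 0.324 for TNFRSF13B. Of 1050 values of 60 named genes in NIKsh, 944 were unchanged, and of 741 values of 42 genes in the line difference 621 were unchanged.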

Other observations

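The lists between untreated lines, the counts per line and the test of NF-kB targets against NTC were chosen after the results were seen. The covariate setting was added then too, alone and with an estimated correlation. Predictions for its test on NF-kB targets and for the splits were written before the outcomes of those tests. The untreated arrays had ACTB ratios from 2.33 to 2.92 in Z-138 and from 3.66 to 6.88 in Maver-1. Apart from the interferon list, the list differences between untreated lines therefore cannot be told apart from RNA signal along transcripts. With doxycycline the ACTB ratio rose in Z-138 NTC, NIKsh#1 and NIKsh#2 (2.33 to 6.34, 2.86 to 4.62 and 2.92 to 5.09). The interferon list's median change there was 0.028, 0.003 and 0.043. It was -0.044 in Maver-1 NTC, where the ratio fell from 6.88 to 4.43. Unless doxycycline hid a move, these values argue against RNA signal as the main source of the -1.44 below. Without doxycycline the interferon response genes were lower in Z-138, with a median of -1.44 over 33 genes (camera adjusted p = 1.18e-06, and adjusted p = 0.0822 with an estimated correlation). Of these genes, 32 passed limma, 29 of them being lower. Examples were HERC5, an ISG15 ligase, at -5.90 ± 0.20, IFI44 at -5.52 ± 0.24, OAS2, a sensor of double-stranded RNA, at -4.34 ± 0.19 and MX2, an antiviral GTPase, at -3.23 ± 0.12. The untreated Z-138 signals of HERC5 (0.6), IFI44 (4.8), OAS2 (11.93) and, below, FCRL1 (3.6) were under the filter signal of 12.55, so the sizes of these differences depend on the pseudocount. B cell identity genes were lower in Z-138 (median -0.35, 22 of 27 passing genes lower, adjusted p = 0.0121, and adjusted p = 0.515 with an estimated correlation), with the germinal centre repressor BCL6 at -3.73 ± 0.21 and FCRL1 at -4.24 ± 0.33. Plasma cell genes were higher (median 0.35, 12 of 17 higher, adjusted p = 0.0318, and adjusted p = 0.625 with an estimated correlation), with FKBP11, a chaperone of the secretory pathway, at 1.67 ± 0.09 and PRDM1, the driver of plasma cell fate, at 1.75 ± 0.11. The p53 targets (median 0.37, 14 of 18 higher) and the ATF4 stress response (median 0.18, 13 of 15 higher) each had an adjusted p of 0.0128, with adjusted p = 0.33 and 0.748 with an estimated correlation. By camera the other 20 lists did not pass, while 16 of the 25 passed fry and 0 camera with an estimated correlation. Among the 20 were T and NK cell markers at a median of 0.42 (camera adjusted p = 0.0865, fry 3.18e-05) and NF-kB targets at a median of -0.32 and a mean of -0.04 with camera pointing up (adjusted p = 0.844, fry 0.979).

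In Z-138 alone, limma called 247 genes in the 2 NIKsh cultures, 122 higher and 125 lower, and in Maver-1 0 (459 at an unadjusted p under 0.05), a contrast that is tested gene by gene only by the 14 line differences. The genes named next are examples chosen after their values were seen. Among those higher were RGS13, a regulator of G protein signalling, at 3.27 ± 0.34, THSD7A at 3.24 ± 0.30, RASGEF1B at 2.53 ± 0.28, FGFR3, a growth factor receptor, at 2.11 ± 0.24 and TLR10 at 1.91 ± 0.23, of which RGS13, THSD7A and RASGEF1B had untreated Z-138 signals of at most 5.7, 17.8 and 12.8. Among those lower were EPB41L4B at -3.22 ± 0.31, RASGRP3, an activator of RAS in B cells, at -2.79 ± 0.26, PTPN3, a phosphatase, at -2.77 ± 0.25, CD80 at -2.02 ± 0.31 and CD40 at -1.88 ± 0.26. Of 44 NF-kB targets 7 fell (CD40, CD80, IL10, NFKBIA, PLEK, RELB and TNFAIP3) and RGS1 rose. Of the 247 genes 202 had the same sign in the Maver-1 mean, and 46 also passed in the same direction against the Z-138 NTC pair, a single pair assumed to vary like the others. The ACTB ratio was higher with doxycycline in these same Z-138 pairs, and with it as a covariate limma called 0 genes in Z-138 (283 at an unadjusted p under 0.05) and 3 in Maver-1. For the 247 genes the median size went from 1.28 to 1.16 and the median standard error from 0.20 to 1.88 at 1 residual degree of freedom, with 198 keeping their sign, so the count of 0 by itself decides nothing about RNA signal. The Z-138 count was 164 without the filter, 155 at the 75th percentile and 118 with averaged probe sets.

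One hypothesis is that the lower NF-kB target genes in NIKsh cultures may follow from lower NIK, which was not measured as protein, as the list's median was negative in each of the 4 cultures and MAP3K14 mRNA was at -0.681, -0.075, -0.437 and -0.488 without passing (adjusted p = 0.529). Its test would be NIK protein in these cultures, and the list after a hairpin-resistant MAP3K14 is put back. A difference in 3' to 5' RNA signal as the whole cause is argued against by the median of -0.292 with the ACTB ratio as a covariate (camera adjusted p = 2.84e-06, and adjusted p = 0.399 with an estimated correlation), against -0.302 without it (adjusted p = 0.186 with an estimated correlation), while the covariate moved single NIKsh effects by a median of 0.062, and by the Maver-1 NIKsh medians of -0.22 and -0.23 at nearly flat ratios. Doxycycline or hairpin induction as such is argued against by the difference from NTC (camera adjusted p = 2.93e-05), where the adjusted p = 0.289 with an estimated correlation leaves the size of that evidence open. The NTC pairs also had the widest ACTB moves of each line, from 2.33 to 6.34 in Z-138 and from 6.88 to 4.43 in Maver-1. The part of these moves in the difference from NTC was not tested. Off-target effects shared by both hairpins and slower growth were not tested.

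Reassigning doxycycline within the 4 NIKsh pairs gives 8 assignments, too few for a share under 0.05, and the real one, with 5 genes, was the 1 with as many, the highest other giving 0. For the untreated lines the 10 splits of 6 arrays are also too few for a share under 0.05, and the real split, with 6956 genes, was the 1 with as many, the highest other giving 0. Every other split mixes the lines within a group, so the line differences widen its spread. Its count of 0 therefore says little about chance.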
